A study of Mus musculus with 24 samples.

How the data were processed

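Total RNA of undifferentiated 129/Sv mouse embryonic stem cells was hybridised to 24 Affymetrix MG 430 2.0 arrays, 1 colour and 1 sample per array. The values analysed were the deposited log2 expression values of 45101 probe sets per array, made by the authors with GCRMA, per the submitters' processing notes. GCRMA adjusts the background by probe sequence, normalizes arrays against each other and summarises the probes of a probe set. Its version, the chip definition and whether all arrays were processed together are not given in the sources used here. The log2 scale was read from the values, which ran from -0.18 to 17.19 with array medians of 3.33 to 3.60. No 2 arrays held identical values.

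Groups followed the titles and the group and genotype characteristics of the labels: control, knock-out and the knock-in lines Q20, Q50, Q91 and Q111. The description field of the labels contradicts both: it calls the control arrays cells without Hdh and the knock-out arrays the reverse. The repeat number of each knock-in array was that of its longer allele in the genotype label.

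The 64 AFFX control probe sets were left out, and of the remaining 45037 the 17980 (39.9%) with a log2 value of 5 or more on at least 3 of the 24 arrays were tested, a filter blind to the groups. GEO's platform annotation gave 1 gene for 34945 probe sets and several for 932, and 9160 were unnamed here. Genes were named only from probe sets with 1 gene. Where a gene had several, the probe set with the highest mean over all arrays stood for it, which left 9504 genes. Chromosomes and neighbouring genes were taken from a RefSeq table of assembly GRCm38.p6, and no coordinates are given because the data name no build. Genes with probe sets called in opposite directions numbered 6 for the knock-out, 10 for Q20, 3 for Q50, 3 for Q91, 9 for Q111, 26 for knock-out against Q111 and 0 for the trend.

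All 24 arrays entered a single limma fit (R 4.3.3, limma 3.58.1) with a mean per group and 18 residual degrees of freedom. Two-sided moderated tests gave the knock-out against control, each line against control and the knock-out against Q111. Benjamini-Hochberg adjustment ran over all 17980 probe sets, with a threshold of 0.05. The 12 knock-in arrays alone gave the slope of the log2 value on the repeat number, printed per 100 repeats, and a moderated F-test of any difference among the 4 lines. Arrays are nested in lines, so repeat length and line cannot be separated within a line. Values for single probe sets of Htt and for chromosome medians were also compared by exact permutation tests, two-sided, whose smallest possible p was 0.00216 for 6 arrays against 6 and 0.0119 for 6 against 3. A correlation across arrays used 100000 permutations. The number of arrays limits the precision of every value.

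Because the lines and the knock-out shared 6 controls, correlations between their changes were set beside 200 simulated draws of unchanged groups and beside estimates with the controls split in all 20 ordered ways. The knock-out change was also set against the repeat slope, which shares no array with it, and against the 24 possible orders of the lines.

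26 gene lists were fixed before the data were examined: pluripotency, primed epiblast, neuroectoderm, mesoderm, primitive and definitive endoderm, trophoblast, fibroblast (feeder) markers, two-cell-like, REST-regulated neuronal genes, p53 targets, cholesterol biosynthesis, oxidative phosphorylation, glycolysis, hypoxia response, heat shock proteins and cochaperones, unfolded protein and integrated stress response, proteasome subunits, autophagy and lysosome, Wnt/beta-catenin targets, imprinted genes, Y-linked and X-inactivation genes, cell cycle, neighbours of the huntingtin gene, huntingtin-binding proteins, NRF2 antioxidant genes and interferon response. Members past the threshold were counted over all probe sets and adjusted over the list alone. limma's camera compared each list with the other genes, with a preset correlation of 0.01 between genes and again with an estimated one. It was adjusted over the 25 lists with at least 3 members measured, and the two-cell-like list had 2.

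Named genes followed a rule set before the data were examined. For the knock-out and the trend these were the 10 largest rises and 10 largest falls past the threshold. Every knock-out array had to lie beyond every control array, and for the trend the 4 line means had to follow the repeat order. For each line and for knock-out against Q111 these were the 5 largest of each direction. For a RIKEN or Gm symbol the next gene was taken as well. For each list described, 2 to 4 members with the smallest p were added, and Htt always. Lists not past camera that are described gene by gene were chosen after their values were seen.

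The fits were tested on simulated data of the same size, with 50 probe sets changed at each of 4 sizes. Of changes of 0.5, 1, 2 and 3 in log2, the knock-out fit recovered 44%, 82%, 98% and 100%, with 7 calls among unchanged probe sets. The Q111 fit recovered 28%, 64%, 96% and 98%, with 8 such calls. The trend fit recovered 8%, 54%, 94% and 98% for changes per 100 repeats, with 8 such calls.

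Alternatives covered the filter, a second quantile normalization, median centring, the variance model, array weights, averaging of probe sets per gene, a fold minimum, the replicate number as a block, only the groups compared, each array left out in turn, and for the trend the controls, the repeat scale, line as a random block, line means and each line left out. Leaving out chromosomes 1, 8, 11 and 14, dividing the replicates of the knock-out comparison and leaving out single arrays for the lists of each line were added after the data were seen. Figures were drawn with matplotlib 3.10.9.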

Results

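Expression was measured on 24 arrays of undifferentiated 129/Sv mouse embryonic stem cells, which are cultured cells of the early embryo. The groups differ at Hdh, the older name of Htt, the mouse gene of huntingtin, whose CAG repeat is expanded in Huntington's disease. 6 arrays were titled control, with 7 repeats on each allele, and 6 were titled knock-out. 4 knock-in lines of 3 arrays each carried 7 repeats on 1 allele and a longer tract on the other. The longer tract had 16 repeats in Q20, 45 in Q50 (43 in replicate 3), 85 in Q91 and 111 in Q111. Every title calls its array a biological replicate; whether replicates were clones or parallel cultures is not given in the sources used here, so p-values measure only the spread between these arrays.

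From 36.8% (knock-out replicate 1) to 38.0% (Q20 replicate 2) of the probe sets of an array reached a log2 value of 5. Arrays of 1 group correlated across probe sets with r from 0.979 to 0.995 in controls, 0.986 to 0.995 in knock-outs, 0.972 to 0.990 in Q20, 0.958 to 0.979 in Q50, 0.961 to 0.979 in Q91 and 0.975 to 0.993 in Q111. The first principal component took 47.7% of the variance and ran from -55.23 in a knock-out array to 63.94 in a Q91 array. All controls lay between -35.58 and -21.03 on it, and Q50 spread from -13.30 to 32.33. The Actb probe sets of Q50 replicate 3 differed by 1.54 in log2 between the 3' and 5' ends, against 0.75 to 1.03 on the other arrays, a measure of RNA integrity. Log2 values under the filter's level of 5 were not told from background, so wherever a group mean of a gene lies below it the exact size of a change is not settled. Beyond the genes marked so below, this holds among others for Tm7sf2, Zic2, Col1a1, Col1a2, Rhox6, Fgf5 and Uty in the controls. It also holds for Zic2, Tagln, Thbs1, Col1a1, Col1a2 and Peg10 in the knock-out. In the lines it holds for Col1a2 in Q20, Q50 and Q91, and for 1 Htt probe set in Q111, at 4.98.

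Htt was examined first, because it checks the labels. On the probe set with the highest signal, Htt was 8.01 ± 0.29 (SD, n = 6) in the control arrays and 7.21 ± 0.27 (SD, n = 6) in the knock-out arrays. The fall by 0.80 had a standard error of 0.16 and an adjusted p of 0.00195, and all 6 knock-out arrays lay below all 6 controls (exact permutation p = 0.00216, the smallest this design can give). The 6 control arrays held 8.01, 8.14, 8.16, 7.45, 8.25 and 8.05, and the 6 knock-out arrays 7.39, 6.67, 7.31, 7.31, 7.33 and 7.27. The 3 arrays of Q20 held 7.69, 7.25 and 7.68, those of Q50 7.44, 7.42 and 7.34, those of Q91 6.67, 6.83 and 7.39, and those of Q111 7.39, 6.84 and 7.42.

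The direction goes with the titles and against the description field, but it is weak evidence. The knock-out retained 57.6% of the control signal, and the knock-in lines, which keep both alleles, fell to a similar level. Htt fell by 1.05 in Q91 (adjusted p = 0.000565) and by 0.79 in Q111 (adjusted p = 0.00445). The changes of -0.61 in Q50 (adjusted p = 0.0544) and -0.47 in Q20 (adjusted p = 0.0777) did not pass in limma. Their exact permutation p was 0.0119 in Q50 and 0.0476 in Q20, or 0.0298 and 0.0866 adjusted over the Htt tests. On the second strongest Htt probe set, with a control mean of 6.39, the knock-out change was 0.26 (adjusted p = 0.211). On the third, with a control mean of 5.83, it was -0.30 (limma adjusted p = 0.0540, exact permutation p = 0.0173, or 0.0385 adjusted over the Htt tests). The fourth, with a change of 0.05, stayed below the filter. Which part of Htt was deleted is not given in the sources used here, and a probe set outside the deleted part checks nothing. The genes next to Htt gave no wider fall in the knock-out: of 6 neighbours of the huntingtin gene measured, 0 rose and 1 fell, with a median change of -0.07 (camera adjusted p = 0.420).

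**Figure D1:**
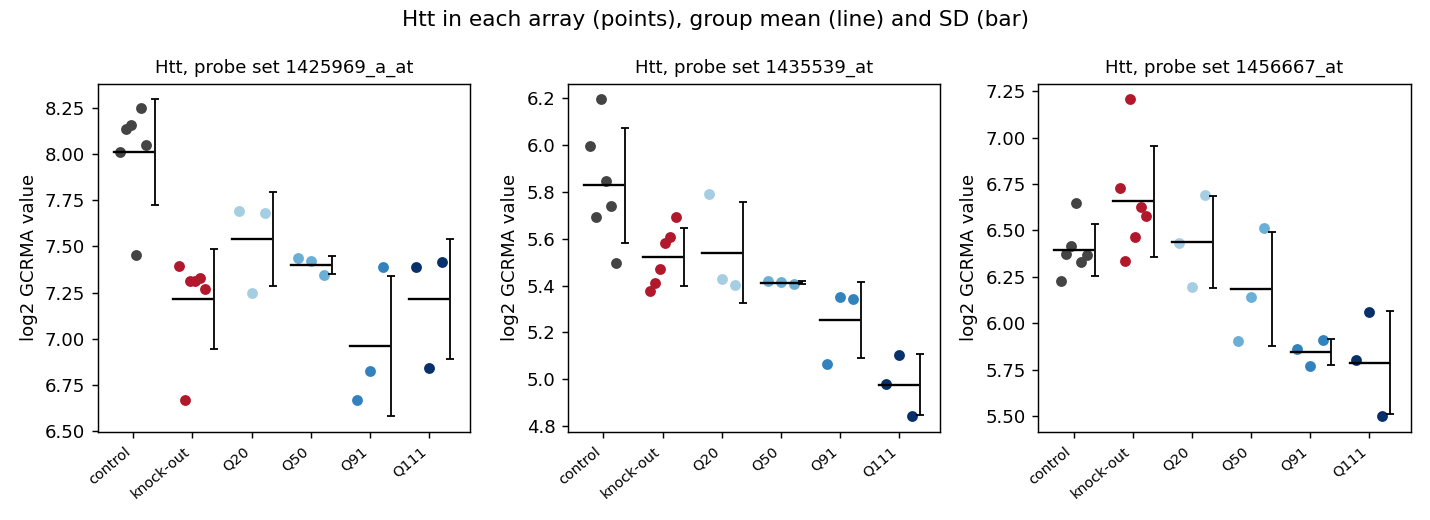
Log2 GCRMA values of 3 Htt probe sets in each array (points) by group, with the group mean (line) and SD (bar). On the strongest probe set the control mean is 8.01 and the knock-out mean 7.21, whereas on the second strongest the knock-out mean of 6.66 lies above the control mean of 6.39.

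The knock-out against control comparison addresses which genes differ in the knock-out arrays, where loss of Htt and clone cannot be separated. The largest change was in Mest, an imprinted gene expressed from the paternal allele, which fell by 7.84 (SE 0.27, adjusted p = 3.85e-14), from 11.11 ± 0.40 (SD, n = 6) to 3.27 ± 0.39 (SD, n = 6). Lrp2, an endocytic receptor, fell by 3.63 (SE 0.43) from 8.17 to 4.54. Pla2g1b, a phospholipase, fell by 4.46 and the X-linked Fmr1nb fell by 4.11. The noncoding Lncenc1 fell by 3.59, the Polycomb gene Sfmbt2 by 3.26 and Glipr2 by 2.87. The uncharacterised 1700097N02Rik fell by 2.84, the titin gene Ttn by 2.78, the germline gene Tdrd12 by 2.70 and Parp12 by 2.67. The largest rise was in Bhlhe40, a transcription factor of circadian and hypoxic control, by 2.87 (SE 0.47, adjusted p = 0.000495), from 6.66 ± 0.90 to 9.53 ± 0.38 (SD, n = 6). Ccdc18 rose by 2.85, the cholesterol transporter Abca1 by 2.64, Arap2 by 2.26, Elf1 by 2.02 and Kbtbd11 by 1.91. The prolyl hydroxylase gene Egln3 rose by 1.87, the transglutaminase gene Tgm2 by 1.85, the Nodal antagonist Lefty2 by 1.79 and Perp by 1.78. Arap2 in controls and Mest, Fmr1nb, Lrp2, Glipr2 and Ttn in the knock-out had means below the filter's level of 5, so the exact sizes of these changes depend on the floor of the signal. All 20 characterised genes named passed with every knock-out array beyond every control array.

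limma called 2624 probe sets, 1335 higher and 1289 lower, of which 374 changed at least 2-fold. Over genes these were 718 higher and 837 lower of 9504. The number of calls was 3484 with replicates 1 to 3 of both groups alone and 1306 with replicates 4 to 6 alone. These sets of replicates stood apart in some values. In the controls, Lrp2 was at 8.97, 8.77 and 8.97, then at 7.53, 7.41 and 7.37. In the knock-outs, the median of chromosome 14 genes over the control mean was 0.37, 0.31 and 0.38, then 0.53, 0.53 and 0.53. The knock-out tests take the 6 arrays of a group as independent, so their p-values and standard errors may overstate the replication.

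Cholesterol biosynthesis rose in the knock-out as a list: 10 of 20 members measured were higher and 0 lower over all probe sets, and 12 and 0 adjusted over the list alone, with a median change of 0.39. Nsdhl rose by 0.53, Fdft1 by 0.66, Msmo1 by 0.66 and Tm7sf2 by 1.36. Camera gave an adjusted p of 6.97e-07, and an adjusted p = 0.342 with an estimated correlation. The unfolded protein and integrated stress response list went lower, with 0 of 22 members higher and 8 lower (1 and 10 adjusted over the list alone) and a median of -0.27. Mthfd2 fell by 1.13, Chac1 by 0.88, Asns by 0.68 and Psat1 by 0.51. Camera gave 0.00118, and an adjusted p = 0.319 with an estimated correlation. Among 14 hypoxia response genes 4 were higher and 1 lower (6 and 1 adjusted over the list alone; median 0.51). Ero1a rose by 0.88, beside Bhlhe40 and Egln3, while Kdm3a fell by 0.51. Of 17 glycolysis genes 3 were higher and 1 lower (4 and 1 adjusted over the list alone; median 0.22). Hk2 rose by 0.63, Slc2a1 by 0.62 and Pfkl by 0.58, and Eno3 fell by 0.71. Both lists had a camera adjusted p of 0.0403, and an adjusted p = 0.564 with an estimated correlation. Leaving out any 1 of replicates 1 to 3 of either group ended both calls. On both lists some controls overlapped the knock-outs. The mean change of the hypoxia genes was 0.58 and 0.51 in control replicates 5 and 6, and from 0.25 to 0.76 in the knock-outs. For glycolysis it was 0.29 and 0.26 in these controls, and from 0.11 to 0.28 in the knock-outs.

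Several lists held called members in the knock-out without passing camera. Of 14 primed epiblast genes, which mark the state after implantation, 4 were lower and 0 higher, the same adjusted over the list alone: Dnmt3b fell by 1.18, Pou3f1 by 1.53, Dnmt3a by 1.44 and Zic5 by 0.89 (camera adjusted p = 0.0595). Of 27 pluripotency genes 2 were higher and 1 lower (camera adjusted p = 0.356). Of 21 NRF2 antioxidant genes 5 were higher and 0 lower, with Tkt up by 0.49, Cat by 0.70, Gclc by 0.63 and Srxn1 by 0.96 (camera adjusted p = 0.0606). Of 18 p53 targets 3 were higher, among them Trp53inp1 by 0.64 and Phlda3 by 0.56, and Rrm2b did not pass with a change of -0.41 (camera adjusted p = 0.0925). Beside Mest, the imprinted genes gave a fall of Peg3 by 1.00 and a rise of Gnas by 1.11. Peg10 did not pass with a change of -1.68 (camera adjusted p = 0.194; 1 of 23 higher and 2 lower).

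Each knock-in line against control addresses what a targeted allele of a given length changes; line and repeat length cannot be separated in any of the 4. In Q20, with 16 repeats, Thbs1, a matrix glycoprotein, rose by 6.67 (SE 0.75, adjusted p = 8.83e-06), from 3.20 ± 0.37 (SD, n = 6) to 9.87 ± 1.95 (SD, n = 3), and the actin-binding Tagln by 6.55. The imprinted Nnat rose by 6.34, the interferon-inducible Gbp2b by 5.85 and Phldb2 by 5.41. The control means of these 5 genes, and the Q20 means of Nkx6-3 and Dixdc1, lay below the filter's level of 5, so the exact sizes and the order of their changes depend on the floor of the signal. Inhbb, an activin subunit, fell by 5.69 (SE 0.62, adjusted p = 7.67e-06), from 11.10 ± 0.61 (SD, n = 6) to 5.41 ± 1.14 (SD, n = 3). Nkx6-3 fell by 4.86, Tgfbi by 3.36, Cacna2d2 by 3.13 and Dixdc1 by 2.96. limma called 4539 probe sets, 2921 higher and 1618 lower. This split depended on the scaling: quantile normalization gave 2356 higher and 2851 lower, and median centring 2205 higher and 2827 lower. The median of the tested probe sets lay 0.11 above the controls in Q20 and 0.12 above them in Q111, which centring removes.

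Pluripotency genes fell in Q20, with 2 of 27 higher and 13 lower (3 and 16 adjusted over the list alone; median -0.44). Klf4 fell by 1.23, Esrrb by 1.37, Tfcp2l1 by 1.93 and Tet2 by 1.25. The mean change of this list was -0.58 and -0.68 in replicates 1 and 2 but -0.20 in replicate 3. Primed epiblast genes rose, 9 of 14 higher and 0 lower (11 and 1 adjusted over the list alone; median 1.41), with Pou3f1 up by 2.42, Krt18 by 4.24, Dnmt3b by 1.16 and Zic2 by 1.79. Camera gave 1.23e-04 and 5.67e-05 for these lists, and an adjusted p = 0.324 and an adjusted p = 0.174 with an estimated correlation. Of 14 fibroblast (feeder) markers measured of 30 listed, 11 were higher and 0 lower (12 and 0 adjusted over the list alone; median 1.79), with Ccn2 up by 4.23 and Col1a1 by 4.25. Camera gave 1.97e-06, and an adjusted p = 0.245 with an estimated correlation. The filter shaped these values: 14 listed markers lay below it, such as Dcn at 2.22 and Lum at 2.38 in Q20. Col1a1, Col1a2, Col5a2, Tagln and Thbs1 passed it with control and knock-out means under 5, so mainly through knock-in arrays. The counts, medians and camera values of this list, also in Q91 and Q111, are therefore in part set by the filter. Imprinted genes rose, 15 of 23 higher and 2 lower (15 and 3 adjusted over the list alone; median 1.08): Peg3 rose by 1.87, the noncoding Rian by 1.88 and Impact by 1.34. Camera gave 5.67e-05, and an adjusted p = 0.174 with an estimated correlation. Oxidative phosphorylation genes fell by a smaller amount, 0 of 41 higher and 15 lower (0 and 21 adjusted over the list alone; median -0.21). Cox5b fell by 1.04, Sdhc by 0.95, Ndufb8 by 0.66 and Uqcrc1 by 0.62. Camera gave 6.55e-07, and an adjusted p = 0.335 with an estimated correlation. Interferon response genes gave 7 of 11 higher and 1 lower (7 and 1 adjusted over the list alone; median 0.72), with Irf1 up by 1.77, Bst2 by 1.31, H2-K1 by 1.00 and Ifitm1 by 0.72. Camera gave 0.0333, and an adjusted p = 0.245 with an estimated correlation. Of 27 interferon response genes listed, 13 lay below the filter. Ifit1, Ifit3, Irf7, Mx1, Rsad2 and Usp18 were under 3 in controls, Q20 and Q111. Oasl2 went from 2.44 in controls to 3.20 in Q20 and 3.31 in Q111, and Psmb9 from 2.08 to 2.49 and 3.29, all below 5. The list values therefore cover only its measured members. Of 18 p53 targets 7 were higher and 0 lower, with Ccng1 up by 1.48, Plk2 by 2.54, Trp53inp1 by 0.86 and Mdm2 by 0.76, but the list did not pass (camera adjusted p = 0.0935).

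**Figure D2:**
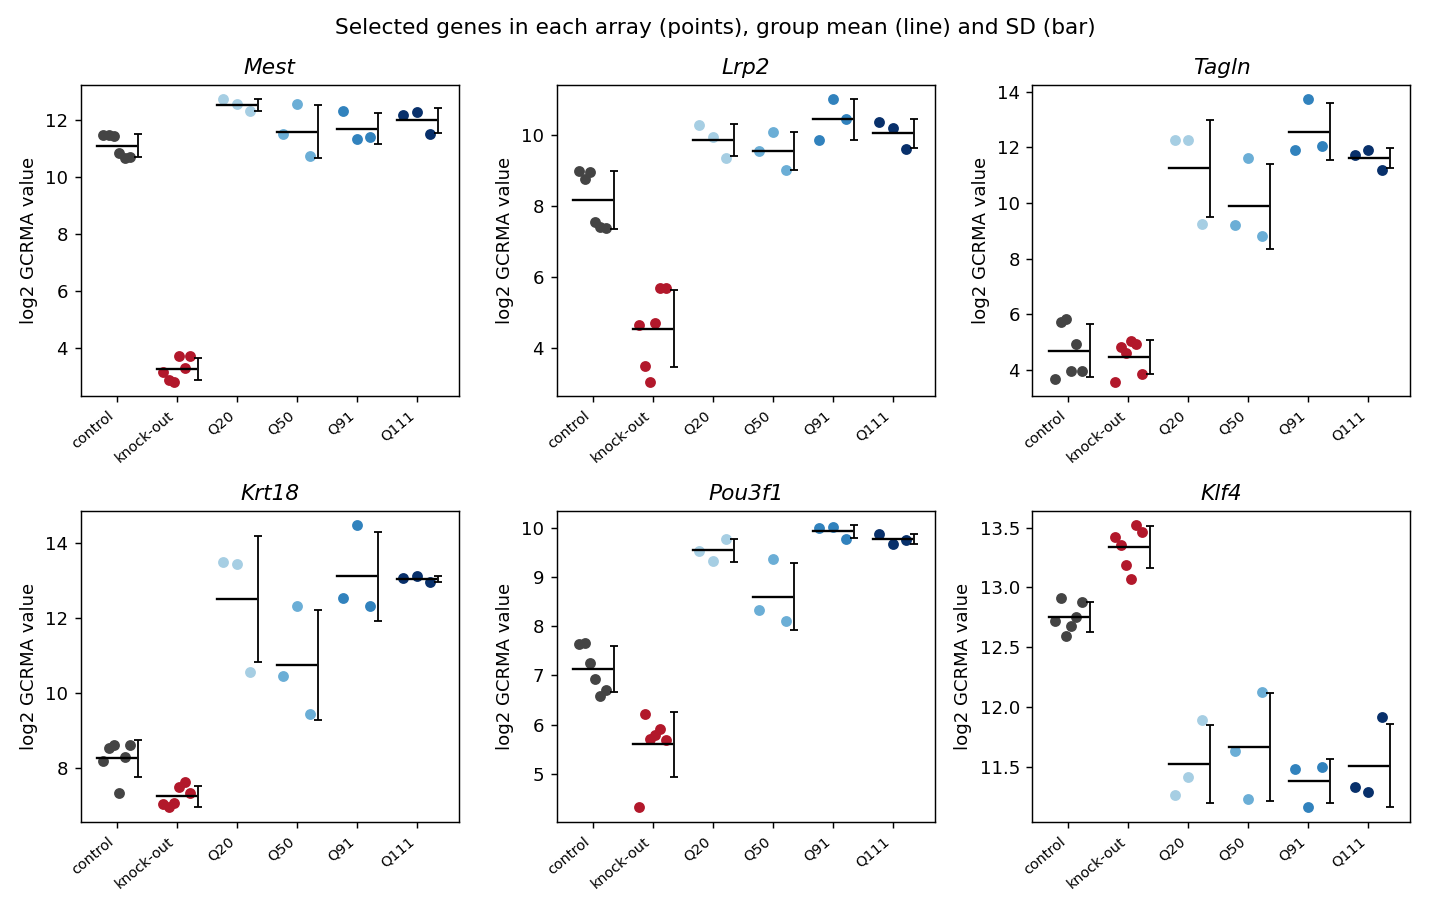
Log2 GCRMA values of 6 genes in each array (points) by group, with the group mean (line) and SD (bar). Mest is at 3.27 in the knock-out and at 11.11 or more in every other group; Tagln is at 4.69 in controls and at 9.89 or more in every knock-in line.

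In Q50, with 45 repeats, Tagln and Thbs1 were again among the largest rises. Tagln rose by 5.19 (SE 0.68, adjusted p = 0.000285), from 4.69 ± 0.95 (SD, n = 6) to 9.89 ± 1.52 (SD, n = 3), the myosin light chain gene Myl9 by 4.23 and Thbs1 by 4.17. The tight junction gene Cldn6 rose by 3.73 and the iron exporter gene Slc40a1 by 3.71. Smarcd3, a subunit of a chromatin remodelling complex, fell by 2.18 (SE 0.43, adjusted p = 0.00448), Itpka by 1.96, the cyclin gene Ccnd2 by 1.83, Aff1 by 1.50, and Scn2b fell by 1.47. limma called 1438 probe sets, 1024 higher and 414 lower, the fewest of the 4 lines; quantile normalization gave 692 higher and 746 lower, and median centring 673 higher and 724 lower. Without Q50 replicate 2 the count was 739, and with only the 2 groups in the fit it was 601. The control means of Tagln, Myl9, Thbs1 and Slc40a1 and the Q50 mean of Scn2b lay below 5, so the exact sizes and order of these changes are not settled. Q50 replicate 3, with the high Actb difference, also stood apart on the third principal component, at -74.59 against -26.43 to 20.36 on the other arrays. Without it 10 lists passed camera in Q50 in place of 5, and without Q50 replicate 2 only 3, when primed epiblast and trophoblast genes no longer passed; both settings were chosen after the data were seen.

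Primed epiblast genes rose in Q50, 4 of 14 higher and 0 lower (6 and 0 adjusted over the list alone; median 0.79): beside Cldn6, Pou3f1 rose by 1.48, Krt18 by 2.48 and Sall2 by 1.37. Camera gave 0.00496, and an adjusted p = 0.438 with an estimated correlation. Trophoblast genes gave 3 of 9 higher and 0 lower (5 and 0 adjusted over the list alone; median 1.42), with Rhox6 up by 1.69 and Krt8 by 2.62, and Krt18 shared with the primed list; Fgfr2 did not pass with 1.26. Camera gave 0.0425, and an adjusted p = 0.219 with an estimated correlation. Of p53 targets, 4 of 18 were higher and 0 lower (9 and 0 adjusted over the list alone; median 0.38), with Trp53inp1 up by 1.31, Plk2 by 2.61, Ccng1 by 0.89 and Eda2r by 1.07. Camera gave 2.54e-04, and an adjusted p = 0.632 with an estimated correlation. The stress response list gave 1 of 22 higher and 8 lower (1 and 10 adjusted over the list alone; median -0.29): Nupr1 fell by 1.46, Chac1 by 0.90, Shmt2 by 0.51 and Phgdh by 0.47. Camera gave 1.22e-04, and an adjusted p = 0.144 with an estimated correlation. Oxidative phosphorylation gave 0 of 41 higher and 5 lower (0 and 8 adjusted over the list alone; median -0.09), with Sdhc down by a log2 change of -0.72 and Cox5a of -0.26. Camera gave 3.21e-05, and an adjusted p = 0.640 with an estimated correlation. The fibroblast markers did not pass in Q50 (median 0.32, camera adjusted p = 0.0710).

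In Q91, with 85 repeats, Tagln rose by 7.87 (SE 0.68, adjusted p = 2.30e-07), from 4.69 ± 0.95 (SD, n = 6) to 12.56 ± 1.01 (SD, n = 3). Thbs1 rose by 7.46, Phldb2 by 6.57, the skeletal actin gene Acta1 by 6.02 and Myl9 by 5.91. The predicted gene Gm6958 fell by 5.77 (SE 0.27, adjusted p = 1.18e-11), from 12.19 ± 0.49 (SD, n = 6) to 6.41 ± 0.04 (SD, n = 3). Nkx6-3 fell by 4.81, Inhbb by 3.51, Dixdc1 by 3.15, Klf15 by 2.95 and Prdm14, a regulator of naive pluripotency, by 2.75. limma called 3988 probe sets, 2281 higher and 1707 lower; quantile normalization gave 1959 higher and 2337 lower, and median centring 1854 higher and 2424 lower. Without Q91 replicate 2 the count was 2204. The control means of all 5 risen genes and the Q91 means of Nkx6-3, Dixdc1 and Klf15 lay below 5, so the sizes and order of these changes are not settled either.

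Pluripotency genes fell in Q91, 1 of 27 higher and 13 lower (1 and 13 adjusted over the list alone; median -0.55): Klf2 fell by 1.48, Klf4 by 1.38, Tcl1 by 1.92 and Zfp42 by 0.86. Primed epiblast genes gave 8 of 14 higher and 0 lower (9 and 0 adjusted over the list alone; median 1.11), with Krt18 up by 4.86, Cldn6 by 4.72, Pou3f1 by 2.81 and Dnmt3b by 1.40. Camera gave 2.85e-05 and 1.19e-05, and an adjusted p = 0.233 and an adjusted p = 0.0722 with an estimated correlation. Fibroblast markers gave 10 of 14 higher and 0 lower (11 and 0 adjusted over the list alone; median 1.73), with Acta2 up by 4.77 and Ccn2 by 4.09 (camera adjusted p = 4.79e-07, and an adjusted p = 0.157 with an estimated correlation). Of p53 targets 10 of 18 were higher and 0 lower (12 and 0 adjusted over the list alone; median 0.76), with Plk2 up by 3.68, Ccng1 by 1.57, Trp53inp1 by 1.56 and Mdm2 by 1.08 (camera adjusted p = 1.19e-05, and an adjusted p = 0.233 with an estimated correlation). The stress response list gave 3 of 22 higher and 12 lower (4 and 12 adjusted over the list alone; median -0.60): Nupr1 fell by 2.53, Chac1 by 1.38, Shmt2 by 0.91 and Slc3a2 by 0.50 (camera adjusted p = 7.98e-05, and an adjusted p = 0.0722 with an estimated correlation). Imprinted genes gave 12 of 23 higher and 0 lower (14 and 0 adjusted over the list alone; median 0.92), with Nnat up by 5.58, Peg3 by 1.20, Impact by 1.02 and Slc38a4 by 0.98 (camera adjusted p = 6.39e-06, and an adjusted p = 0.0722 with an estimated correlation). Oxidative phosphorylation gave 0 of 41 higher and 10 lower, the same adjusted over the list alone (median -0.19): Atp5o fell by 0.77 and Ndufb8 by 0.64 (camera adjusted p = 1.19e-05, and an adjusted p = 0.472 with an estimated correlation). The trophoblast list did not pass (camera adjusted p = 0.0593), though Krt8 rose by 4.99, Krt19 by 3.80 and Fgfr2 by 1.31.

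In Q111, with 111 repeats, Tagln rose by 6.92 (SE 0.68, adjusted p = 1.08e-06), from 4.69 ± 0.95 (SD, n = 6) to 11.61 ± 0.36 (SD, n = 3). Thbs1 rose by 6.66, Nnat by 6.28, Gbp2b by 6.27 and Phldb2 by 6.14. Gm6958 fell by 6.62 (SE 0.27, adjusted p = 7.53e-13), to 5.56 ± 0.67 (SD, n = 3). Nkx6-3 fell by 4.87, Inhbb by 4.06, the small GTPase gene Mras by 3.87, the fusion peptide gene Mymx by 3.28 and Smarcd3 by 3.17. limma called 4615 probe sets, 2909 higher and 1706 lower; quantile normalization gave 2393 higher and 3109 lower, and median centring 2200 higher and 3161 lower. The control means of all 5 risen genes and the Q111 means of Nkx6-3 and Smarcd3 lay below 5, with the same limit. Without Q111 replicate 1 the count was 2989, and without Q20 replicate 1 the Q20 count was 2642.

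Pluripotency genes fell in Q111, 1 of 27 higher and 13 lower (3 and 15 adjusted over the list alone; median -0.36): Tfcp2l1 fell by 1.96, Tcl1 by 1.47, Klf4 by 1.25 and Esrrb by 1.24. The mean change of this list was -0.66 and -0.71 in replicates 1 and 2. In replicate 3 it was -0.07, within the control range of -0.07 to 0.07. Primed epiblast genes gave 11 of 14 higher and 0 lower, the same adjusted over the list alone (median 1.81), with Krt18 up by 4.79, Zic2 by 3.50, Fgf5 by 3.50 and Pou3f1 by 2.65. Camera gave 1.47e-04 and 3.58e-07, and an adjusted p = 0.297 and an adjusted p = 0.0740 with an estimated correlation. Fibroblast markers gave 10 of 14 higher and 0 lower, the same adjusted over the list alone (median 2.39), with Col1a1 up by 4.67 and Ccn2 by 4.07 (camera adjusted p = 4.65e-07, and an adjusted p = 0.163 with an estimated correlation). Cholesterol biosynthesis gave 14 of 20 higher and 0 lower (16 and 0 adjusted over the list alone; median 0.74), with Stard4 up by 1.48, Sc5d by 1.39, Cyp51 by 1.37 and Idi1 by 0.78 (camera adjusted p = 3.58e-07, and an adjusted p = 0.163 with an estimated correlation). Imprinted genes gave 13 of 23 higher and 1 lower (16 and 1 adjusted over the list alone; median 0.89), with Magel2 up by 1.59, Impact by 1.45 and Kcnq1ot1 by 1.26 (camera adjusted p = 2.01e-05, and an adjusted p = 0.139 with an estimated correlation). Oxidative phosphorylation gave 0 of 41 higher and 12 lower (0 and 13 adjusted over the list alone; median -0.23): Cox5b fell by 0.92, Uqcrc1 by 0.44, Cox6c by 0.43 and Cox5a by 0.28 (camera adjusted p = 4.98e-06, and an adjusted p = 0.372 with an estimated correlation).

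Cell cycle genes also fell in Q111, 0 of 26 higher and 9 lower (0 and 12 adjusted over the list alone; median -0.20): Rrm2 fell by 0.58, Bub1b by 0.57, Mcm2 by 0.39 and Pcna by 0.38 (camera adjusted p = 0.00625, and an adjusted p = 0.163 with an estimated correlation). Of p53 targets 6 of 18 were higher and 0 lower, the same adjusted over the list alone (median 0.44), with Plk2 up by 2.78, Perp by 1.89, Ccng1 by 1.43 and Trp53inp1 by 1.18 (camera adjusted p = 0.0162, and an adjusted p = 0.514 with an estimated correlation). Glycolysis gave 7 of 17 higher and 1 lower (8 and 1 adjusted over the list alone; median 0.33): the lactate transporter gene Slc16a3 rose by 2.51, Slc2a1 by 0.93 and Tpi1 by 0.93, while Pdk1 fell by 0.53. Interferon response gave 5 of 11 higher and 1 lower (6 and 1 adjusted over the list alone; median 0.96): Irf1 rose by 1.88, Bst2 by 1.69 and H2-D1 by 1.17, while Irf9 fell by 0.75. Camera gave 0.0353 for both lists, and an adjusted p = 0.514 for glycolysis and an adjusted p = 0.254 for interferon with an estimated correlation. Of the trophoblast list the keratin genes Krt8, by 4.87, and Krt19, by 5.17, rose beside Krt18, while Tfap2c did not pass with -0.68, nor did the list by camera. The Y-linked Uty rose by 3.85 and Eif2s3y by 3.02, and Xist did not pass with -0.49 (camera adjusted p = 0.331 for the list). The rise was not particular to Q111: the list median was 2.38 in Q20, 0.11 in Q50 and 1.42 in Q91. In Q50 the mean change of the list was 1.35, 1.97 and -1.80 in replicates 1 to 3. In the knock-out neither Uty (-1.72), Eif2s3y (-0.03) nor Xist (0.39) passed. Eif2s3y depended on the arrays used: with replicates 1 to 3 of both groups alone it was 1.53 higher (limma adjusted p = 0.00119).

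**Figure D3:**
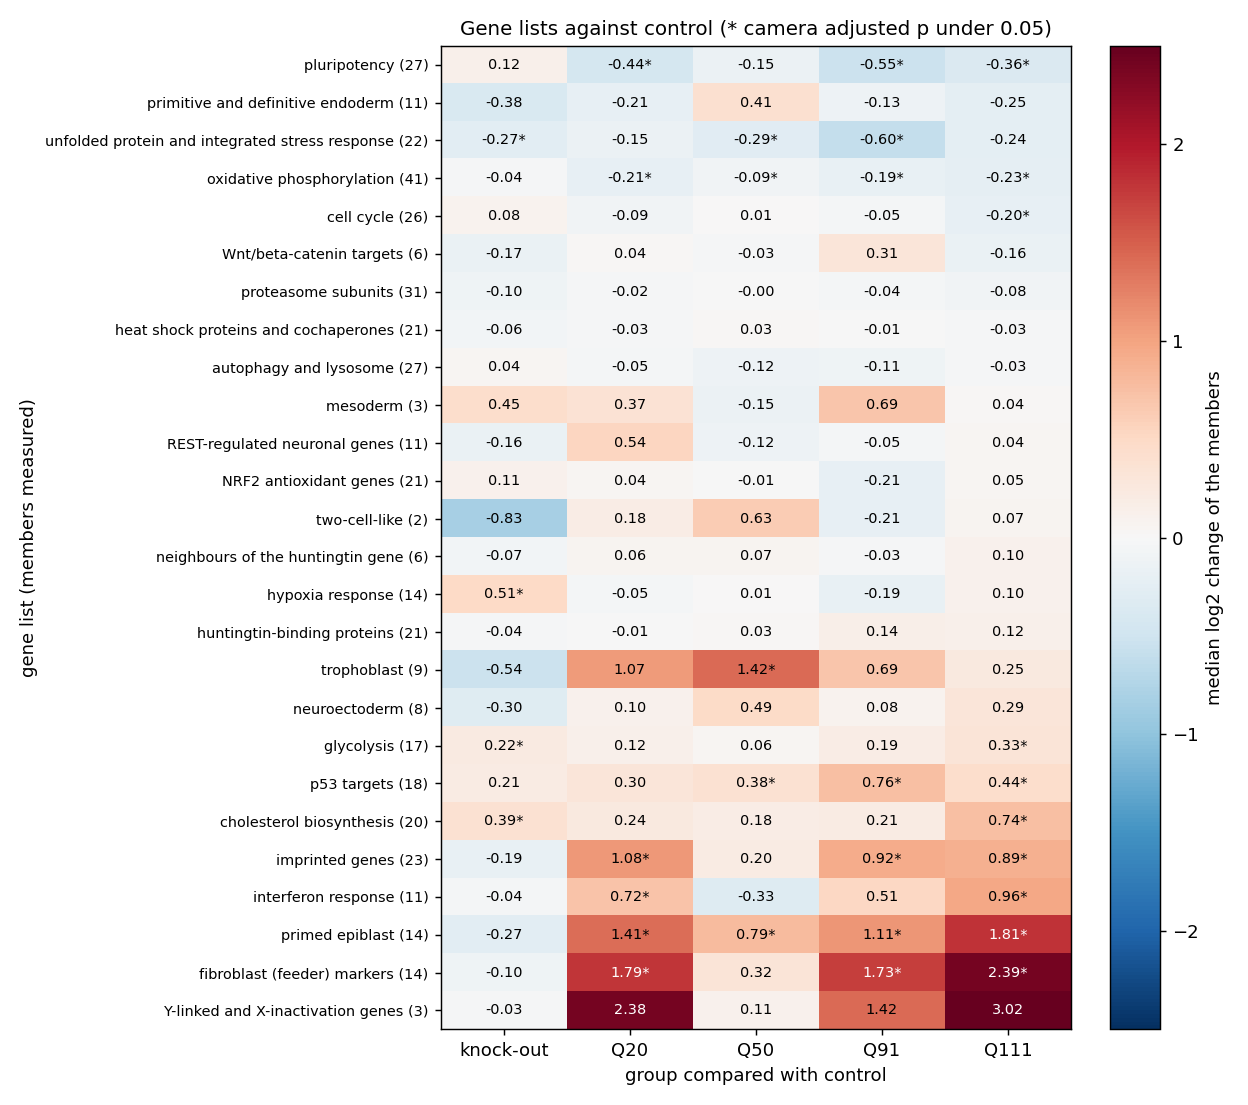
Median log2 change of the measured members (count in brackets) of each of 26 gene lists in 5 groups against control; an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Primed epiblast medians are 1.41, 0.79, 1.11 and 1.81 in the 4 lines and -0.27 in the knock-out.

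Across the 4 lines, 229 genes were called higher and 101 lower in every line. All 4 comparisons use the same 6 controls, so these are not 4 independent findings. Of the 229, 21 were lower and 35 higher in the knock-out, and of the 101, 16 were higher and 17 lower. Over all 9504 genes, 718 were higher and 837 lower in the knock-out, which shares these controls too. Across genes, which are not independent replicates, the knock-out change correlated with the change of Q20 at r = -0.12, Q50 at 0.05, Q91 at -0.03 and Q111 at -0.10. Unchanged groups against the same 6 controls gave a simulated r of 0.41 for each line. No gene changed in that simulation, so its r is larger than shared controls would add among real changes. It is not a like reference for the r values above, for which the split controls and the covariances serve. With the controls split, so that no array was shared, the mean r was -0.15, -0.01, -0.07 and -0.14. The covariance was -0.0327, 0.00928, -0.00808 and -0.0293, against simulated values of 0.0178, 0.0177, 0.0176 and 0.0177, and lay below them in each line. Of the genes called in both comparisons, 187 of 500 went the same way in Q20, 109 of 175 in Q50, 224 of 448 in Q91 and 220 of 533 in Q111. Independent lists would give 204.1, 56.7, 190.1 and 210.1 in the same direction, a figure that leaves out the shared controls, so an excess over it, as in Q50, is not evidence of a shared effect.

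The knock-out against Q111, which uses no controls, addresses how the knock-out arrays and the Q111 arrays differ. Loss of the gene, repeat length and clone cannot be separated in it. Mest fell by 8.73 (SE 0.33, adjusted p = 2.65e-13) relative to Q111 and stood at 3.27 ± 0.39 (SD, n = 6). The keratin gene Krt19 was lower by a log2 change of -7.40, Nnat of -7.35, Pnma5 of -7.14 and Gbp2 of -7.14. Nkx6-3 was higher by 6.65 (SE 0.73, adjusted p = 9.88e-07), at 8.06 ± 0.51 (SD, n = 6) against 1.41 ± 0.05 (SD, n = 3). Nkx6-3 and Abca1 in Q111 and Mest, Krt19, Nnat, Pnma5 and Gbp2 in the knock-out lay below the filter's level of 5, so the exact sizes and the order of these differences are not settled. Gm6958 was higher by 6.25, Inhbb by 4.66, Mras by 4.44, Abca1 by 4.23 and Ccdc18 by 3.67. Against control, Nkx6-3 and Inhbb fell and Nnat rose in Q20 too, whereas Gm6958 stayed at 11.70 there. limma called 6630 probe sets, 2818 higher in the knock-out and 3812 lower; quantile normalization gave 4135 higher and 3163 lower, and median centring 3902 higher and 3062 lower.

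Relative to Q111, 14 of 27 pluripotency genes were higher in the knock-out and 2 lower (16 and 2 adjusted over the list alone; median 0.52): Tfcp2l1 by 2.21, Tcl1 by 1.84 and Klf4 by 1.83 higher, and Lin28a by a change of -0.78. Of 14 primed epiblast genes 0 were higher and 12 lower, the same adjusted over the list alone (median -2.22), with Krt18 at -5.81, Pou3f1 at -4.18, Zic2 at -3.78 and Dnmt3b at -2.49. Camera gave 3.41e-04 and 8.14e-07, and an adjusted p = 0.337 and an adjusted p = 0.0763 with an estimated correlation. Fibroblast markers gave 0 higher and 12 lower of 14, the same adjusted over the list alone (median -2.59; camera adjusted p = 1.21e-05, and an adjusted p = 0.248 with an estimated correlation). Imprinted genes gave 1 of 23 higher and 15 lower (1 and 16 adjusted over the list alone; median -1.08), with Peg3 at -2.11 and Impact at -1.88 (camera adjusted p = 6.24e-05, and an adjusted p = 0.134 with an estimated correlation). Oxidative phosphorylation gave 16 of 41 higher and 2 lower, the same adjusted over the list alone (median 0.16), with Cox5b at 1.13, Cox4i1 at 0.65 and Ndufs3 at 0.55 (camera adjusted p = 5.00e-04, and an adjusted p = 0.580 with an estimated correlation). Cell cycle genes gave 12 of 26 higher and 2 lower (12 and 3 adjusted over the list alone; median 0.33), with Bub1b at 0.88, Rrm2 at 0.72, Pcna at 0.61 and Aurka at 0.49 (camera adjusted p = 0.00138, and an adjusted p = 0.134 with an estimated correlation). Interferon response gave 1 of 11 higher and 7 lower (1 and 8 adjusted over the list alone; median -1.21), with Bst2 at -2.22, Irf1 at -1.93 and H2-D1 at -1.21, and Irf9 at 1.40 against the list (camera adjusted p = 0.0213, and an adjusted p = 0.237 with an estimated correlation).

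The trend over the 12 knock-in arrays addresses which genes follow repeat length. limma called 8 probe sets, 2 higher and 6 lower with length, and 823 at an unadjusted p under 0.05. The calls are weak: limma called 0 with log2 of the repeat number or with the 4 line means, 2 with line as a random block and 0 to 16 with 1 array left out, and 12 of 24 orders of the lines gave as many, so chance cannot be excluded. The naming rule gave Dctn5, a dynactin subunit gene, which fell by 0.88 per 100 repeats (SE 0.12, adjusted p = 0.0320), with line means of 9.54, 9.50, 9.02 and 8.77 from Q20 to Q111 (n = 3 each) and 9.40 in controls. The other 7 were named after their values were seen. Gm6958 fell by 7.61 per 100 repeats, Prune2 by 5.86, Riok3 by 4.26, Mep1b by 2.71, and Resf1 fell by 1.38, while Erdr1 rose by 2.21 and Trub1 by 1.29. Prune2 and Mep1b lay below 5 in Q91 and Q111, so the sizes of their slopes are not settled. The called probe sets of Prune2, Riok3 and Resf1 were not those with the highest signal, which gave slopes of 0.18, 0.32 and -0.54 and were not called. Gm6958 stood at 11.70 in Q20 and 12.10 in Q50 but at 6.41 in Q91 and 5.56 in Q111. A step between Q50 and Q91 left a smaller residual than the slope in 6 of the 8, all but Dctn5 and Resf1. The F-test for any difference among the lines called 30 probe sets (2645 at an unadjusted p under 0.05), and 6 of the 8 were among them. The 30 are not stable: the F-test called from 8 to 496 with 1 array left out and 123 with a replicate block.

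**Figure D4:**
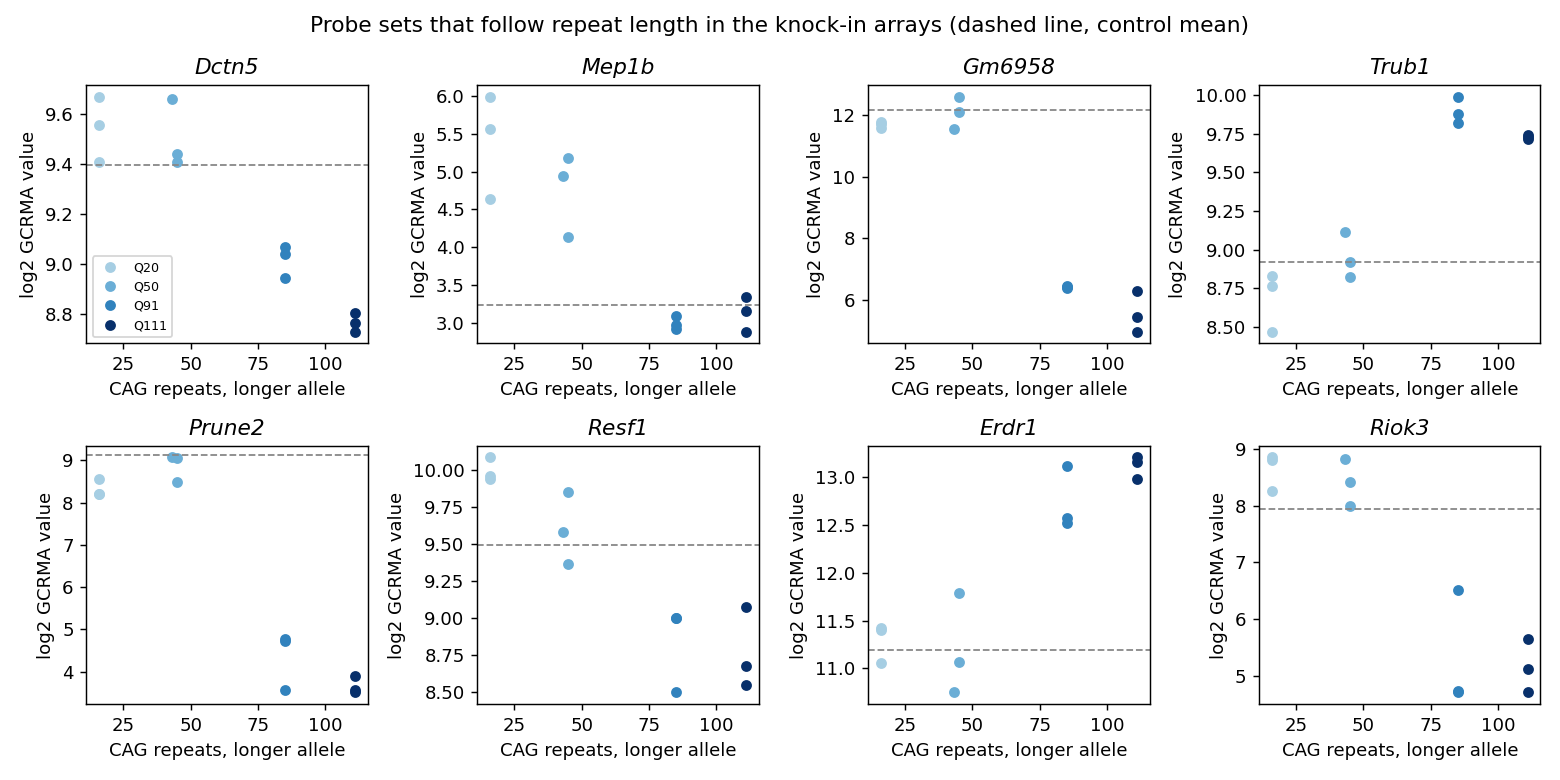
Log2 GCRMA values of the 8 probe sets called for the trend in each knock-in array (points) against the CAG repeats of the longer allele, with the control mean as a dashed line. Dctn5 has line means of 9.54, 9.50, 9.02 and 8.77, and Gm6958 lies at 11.70 and 12.10 in the shorter lines and at 6.41 and 5.56 in the longer ones.

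No list member was called for the trend over all probe sets. Cholesterol biosynthesis had 4 of 20 members higher with length adjusted over the list alone and a median slope of 0.48 per 100 repeats, with Stard4 at 1.10, Sc5d at 0.86, Hmgcs1 at 0.73 and Sqle at 0.61. Camera gave 7.70e-11, and an adjusted p = 0.361 with an estimated correlation. Primed epiblast (median 0.58, camera adjusted p = 5.69e-04), fibroblast markers (0.83, 0.0110), glycolysis (0.26, 2.55e-04) and huntingtin-binding proteins (0.13, 0.0383) had 0 members called adjusted over the list alone. With an estimated correlation these gave an adjusted p = 0.369, an adjusted p = 0.824, an adjusted p = 0.361 and an adjusted p = 0.361. Their leading members were Zic2 at 1.63, Col1a2 at 1.79, Aldoa at 0.40 and Hip1 at 0.73, none of which passed. These slopes depended on Q111: without it Zic2 was at -1.23, and 3 lists passed, 1 higher and 2 lower, in place of 5 higher. Of the huntingtin-binding proteins, which include Hip1r (0.49) and Crebbp (0.26), 0 of 21 were higher and 3 lower in the knock-out, and 4 higher and 1 lower in Q111.

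Htt itself was examined against repeat length over the 12 knock-in arrays on each of its 4 probe sets. On the probe set with a control mean of 5.83 the values fell with length, r = -0.84 (permutation p = 4.00e-05, adjusted over the 4 probe sets 0.000160) and rho = -0.87 (permutation p = 0.000580, adjusted 0.00232). Without the 2 arrays farthest from the median repeat number r was -0.82. On the one with a control mean of 6.39, r was -0.79 (permutation p = 0.00193, adjusted 0.00386) and rho -0.81 (permutation p = 0.00252, adjusted 0.00504), and -0.79 without those arrays. On the probe set with the highest signal r was -0.53 (permutation p = 0.0804) and rho -0.44 (permutation p = 0.154). On the one below the filter r was -0.28 (permutation p = 0.397) and rho -0.13 (permutation p = 0.679). Over all probe sets, limma's adjusted p for the Htt slope was 0.408 and 0.471 on the 2 that correlated. These arrays come from 4 lines, so the permutations count arrays that are not independent of their line.

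Whether the change with repeat length follows the change with loss of the gene was examined across 9504 genes. The knock-out change and the repeat slope correlated at r = -0.02 and rho = 0.002, and all 24 of the 24 orders of the line labels gave an r at least as large in size, from -0.22 to 0.22. The value depended on the lines used: r was -0.16 without Q20, 0.08 without Q50 and 0.14 without Q111. Of 5 genes called for the trend, 1 was also called in the knock-out, against 0.818 for independent lists.

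The remaining lists did not pass camera in any comparison. In the knock-out and in Q111, members higher and lower were 1 and 1, then 3 and 1, of 8 for neuroectoderm; 0 and 0, then 1 and 1, of 3 for mesoderm; and 1 and 2, then 4 and 3, of 11 for primitive and definitive endoderm. They were 0 and 1, then 3 and 2, of 11 for REST-regulated neuronal genes, and 0 and 2, then 4 and 3, of 21 for heat shock proteins and cochaperones. Proteasome subunits gave 3 and 4, then 4 and 4, of 31, and autophagy and lysosome genes 1 and 2, then 6 and 6, of 27. Wnt/beta-catenin targets gave 0 and 1, then 2 and 1, of 6, and neighbours of the huntingtin gene 2 higher and 0 lower of 6 in Q111. The untested two-cell-like list had 1 of 2 members lower in the knock-out and 0 called in Q111. The median of the endoderm list was -0.25 in Q111 and its mean 0.11, and the mesoderm list had a median of 0.04 and a mean of -0.20. The tissue expressed few members of some lists: 14 of 18 mesoderm genes, 14 of 26 REST-regulated genes and 12 of 24 endoderm genes lay below the filter.

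Genes of whole chromosomes shifted together in some arrays. Against control, the genes of chromosome 11 had a median change of 0.49 in Q20 (92.1% of 533 genes higher) and 0.44 in Q111. Those of chromosome 1 had -0.48 in Q20 (88.2% of 357 lower) and those of chromosome 8 -0.47 in Q91 (91.5% of 377 lower). In the knock-out, chromosome 14 had a median of 0.44 (96.9% of 224 genes higher, 143 called higher and 1 lower) and chromosome 11 one of -0.24. Smaller shifts were found on chromosome X, with medians of 0.12 in Q20, 0.21 in Q50, 0.17 in Q91 and 0.13 in Q111, each knock-in array lying above the highest control, and on chromosome 3 in Q50, with 0.11. Each of the shifts named had an exact permutation p at the smallest value its design allows, 0.0119 for 3 arrays and 0.00216 for 6, and 0.108 after adjustment over all chromosomes and groups. Chromosome 1 in Q50, Q91 and Q111 (-0.21, -0.25 and -0.30) and chromosome 14 in Q20, Q91 and Q111 (-0.17, -0.18 and -0.23) had medians of similar or larger size than chromosome X, with exact permutation p of 0.0595 or more. The Q50 value of chromosome 3 is not particular to it. In Q50 replicates 1 to 3 chromosome 3 was at 0.09, 0.07 and 0.19, and chromosome 12 at 0.09, 0.10 and 0.18. In Q50 replicate 3, chromosomes 13, 16 and 18 were at 0.21, 0.22 and 0.20, and chromosome 3 at 0.19. Arrays of 1 line differed, in part by replicate number. Chromosome 8 was at -0.42, -0.32, -0.46 and -0.44 in replicate 3 of Q20, Q50, Q91 and Q111, and between 0.03 and 0.13 in replicates 1 and 2 of Q20, Q50 and Q111, while these were at -0.44 and -0.49 in Q91. Chromosome 1 was at -0.52 in Q111 replicate 1 and at 0.17 in Q111 replicate 3. Chromosomes 1, 8, 11 and 14 held 23.2% of the genes and 29.6% of those called in the knock-out, 32.9% in Q20, 15.8% in Q50, 26.5% in Q91 and 30.4% in Q111.

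**Figure D5:**
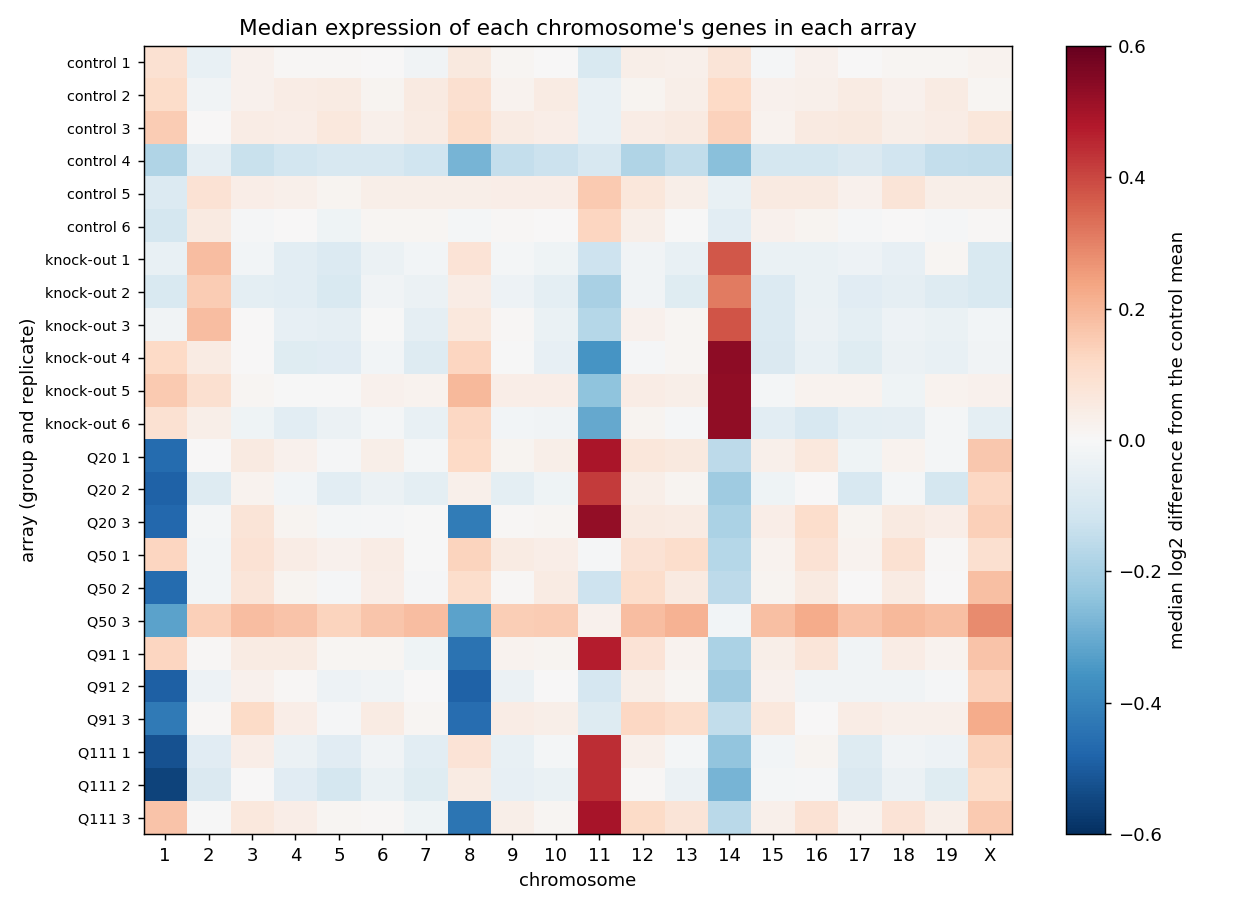
Median log2 difference from the control mean (colour) of the genes of each chromosome (horizontal axis) in each array (vertical axis). Chromosome 14 is higher in all 6 knock-out arrays, and chromosomes 1, 8 and 11 shift by about the same size in some arrays of a knock-in line and not in others.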

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

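Of the tests in this part, none was chosen after its result was seen. 17 of 172 groups of values held an array far from its others by Dixon's test, where 8.6 are expected by chance at 1 in 20 groups. 9 of the 17 concerned control replicate 4, in values that are not independent of each other. Given as the gap to the nearest array over the range of the group, these were 0.702 for Htt, 0.687 for Ccdc18, 0.650 for Tgm2, 0.679 for Perp and 0.649 for Msmo1. The same array gave 0.700 for the mean of the trophoblast list, 0.720 for cholesterol biosynthesis, 0.846 for huntingtin-binding proteins and 0.697 for the median of chromosome 8. Its median was the lowest of the controls on each of chromosomes 1 to 19 and X. These medians over the control mean ran from -0.28 on chromosome 8 to -0.05 on chromosome 2. The chromosome 8 value is thus part of a wider offset of this array, which enters every comparison against control. Control replicate 2 gave 0.695 for the mean of the primed epiblast list.

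Among the knock-out arrays, replicate 5 gave 0.737 for the array median, and replicate 2 gave 0.825 for Htt, at 6.67, and 0.686 for Peg10. Replicate 4 gave 0.721 for Tgm2 and 0.736 for Chac1. Replicate 1 gave 0.716 for Pou3f1, at 4.31, and 0.665 for the mean of the neuroectoderm list.

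A difference between groups led to a closer look at 2 results: the 6630 probe sets called between the knock-out and Q111, and the 30 called for any difference among the knock-in lines. For knock-out against Q111, 1 of 84 splits of the arrays, the real one, gave as many calls, and the highest other gave 2. This excludes a chance division of the arrays only if they are independent, and a chance difference between clones would give the same result. For the differences among lines, 2 of 100 splits, the real one included, gave as many, and the highest other gave 30. These splits take arrays as independent of their replicate number, so chance is excluded at the 0.05 level only if that holds, which is open for these lines.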

How the results depend on the processing

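Most choices were fixed before the data were examined; leaving out chromosomes 1, 8, 11 and 14, dividing the knock-out replicates and leaving out single arrays for the lists of each line were added afterwards. Of the other gene and list values under alternatives fixed beforehand, 4989 and 941 stayed the same, 119 and 74 weakened and 47 and 34 strengthened; under added ones 288 and 1257 stayed the same, 21 and 17 weakened and 3 and 19 strengthened. Signal over background limits weakly expressed genes, such as the Htt probe set below the filter.

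Calls rose with arrayWeights to 5009 for the knock-out, 7280 for Q20, 8359 for Q111, 32 for the trend and 1790 for differences among lines. Averaged per gene, where fewer units are tested, calls were 1631 for the knock-out, 2608 for Q20, 705 for Q50, 2455 for Q91, 2769 for Q111, 3864 for knock-out against Q111 and 11 for differences among lines. With at least a 2-fold change they were 374, 1434, 463, 1413, 1511 and 2117 for the same 6 pairs. Q50 had 601 calls with only the 2 groups compared. Without a filter the trend had 0 and the differences 14, and the differences had 52 with a trended, robust variance. Without chromosomes 1, 8, 11 and 14 the trend had 17 calls, and 8 lists passed in Q50, 8 in Q111 and 3 in the knock-out. There p53 targets, glycolysis and interferon response no longer passed in Q111, nor hypoxia response in the knock-out. Replicates 4 to 6 alone gave 1306 knock-out calls. Replicates 1 to 3, as few, gave 3484. Apart from averaging and the 2-fold minimum, whose construction lowers a count, the cause was not tested.

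For the trend, limma called 878 with the controls added at 7 repeats, 0 with log2 of the repeat number, 2 with line as a random block and 0 with the 4 line means. Without line Q20 it called 3, without Q91 0 and without Q111 0. The knock-out change against the slope had r = -0.0571 over all probe sets, -0.0590 with the controls added, -0.16 without Q20, 0.0841 without Q50 and 0.14 without Q111, and from -0.12 to 0.0637 with 1 array left out. The medians of some lists moved by over 1.5 times when arrays were median centred: oxidative phosphorylation to -0.32 in Q20, -0.17 in Q50, -0.35 in Q111 and 0.26 in knock-out against Q111, and cell cycle to -0.33 and glycolysis to 0.21 in Q111. With an estimated correlation 0 lists passed in every comparison. For the trend 9 lists passed without Q20, 3 without Q50 and 3 without Q111. The other Htt probe sets gave -0.30, 0.0459 and 0.26 in the knock-out.

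With 1 array left out in turn, calls ranged from 1996 to 2275 for the knock-out, 2642 to 4395 for Q20, 739 to 2020 for Q50, 2204 to 4149 for Q91, 2989 to 4627 for Q111 and 5170 to 6357 for knock-out against Q111. They ranged from 0 to 16 for the trend (0 without Q20 replicate 1, 16 without Q50 replicate 3) and from 8 to 496 for differences among lines (8 without Q111 replicate 1, 496 without Q91 replicate 1). Lists past the threshold ranged from 2 to 7 for the knock-out, 6 to 7 for Q20, 3 to 10 for Q50 (3 without Q50 replicate 2, 10 without Q50 replicate 3), 7 to 8 for Q91, 8 to 10 for Q111, 7 to 7 for knock-out against Q111 and 3 to 7 for the trend. The lowest Q20, Q50, Q91 and Q111 counts came without Q20 replicate 1, Q50 replicate 2, Q91 replicate 2 and Q111 replicate 1.

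Eif2s3y in the knock-out, at -0.03 as reported and -0.22 without control replicate 2, reversed to 0.23 with arrayWeights, to 0.02, 0.17 and 0.19 without control replicates 4, 5 and 6, and to 0.05, 0.14 and 0.19 without knock-out replicates 4, 5 and 6. With replicates 1 to 3 alone it was 1.53 (adjusted p = 0.00119), and Xist reversed to -0.10. In the trend Thy1 reversed to -0.39 with the controls added, Sp1 to -0.0691 without Q20, Zic2 to -1.23 and Wnt8a to -0.0588 without Q111, and the interferon response list turned and passed without Q20 (camera adjusted p = 0.0167). Which lists were described gene by gene was chosen after values were seen; among 485 pairs of an undescribed member and a comparison, 54 reversed somewhere, 2 of them past the threshold as reported and 0 under the other setting.

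The labels give groups the same replicate numbers. With a replicate block limma called 2235 for the knock-out, 3399 for Q20, 595 for Q50, 3059 for Q91, 3730 for Q111, 5673 for knock-out against Q111, 4 for the trend and 123 for differences among lines. After removal of group means, control and knock-out arrays of the same number correlated at r from -0.41 to -0.26, and 0 of 12 correlated best with their own number, so the numbers do not pair these arrays. Over all groups 19 of 48 same-numbered pairs had r over 0.1. These include all 3 pairs of Q20 with Q111, at 0.39, 0.46 and 0.39, and all 3 of Q50 with Q91, at 0.32, 0.41 and 0.20, while Q20 with Q50 ran from -0.24 to 0.38. Whether a number marks a shared culture or day in these lines was left open.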

Other observations

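Among the tests in this part, those of normalization, of feeder cells, of repeat length, of divisions of the knock-out arrays and of a step in the trend were chosen after the result was seen; the other tests on chromosomes were written after the shifts were seen but before their own values, and only the splits of the arrays were planned. The lines also differed in genes outside the lists: the called probe sets of Prune2 stood at 8.32 in Q20 and 8.87 in Q50 and at 4.35 in Q91 and 3.66 in Q111, and those of Riok3 at 8.63, 8.40, 5.32 and 5.17. Erdr1 stood at 11.29, 11.20, 12.74 and 13.12. A step between Q50 and Q91 left a smaller residual than the slope in 6 of the 8 trend probe sets, and a model of the step called 43 probe sets, 12 higher and 31 lower. With 4 lines, a step and a slope cannot be told apart.

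Whole chromosomes shifted in expression, which extra or missing copies of chromosomes 1, 8, 11 or 14 in some cultures might explain. For chromosome 1 in Q20, 8 in Q91, 11 in Q111 and 14 in the knock-out, picked after all shifts were seen and 1 per chromosome, each of 4 parts of the chromosome moved the same way, by at least 0.383, where a 3 to 2 copy ratio would give 0.58. Normalization of whole arrays would move the other chromosomes of the same comparisons too, but apart from chromosomes 1, 8, 11 and 14 their median shift was 0.0291 and the largest 0.17. A few strongly changed genes would leave most unmoved, whereas at least 88.2% of the genes of these chromosomes lay on the shifted side. Expression cannot say whether the lines lost or the controls gained a copy, and no count of chromosomes was analysed here.

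With the preset correlation, camera gave a rise of primed epiblast genes in all 4 lines and of fibroblast markers in Q20, Q91 and Q111, though none passed with an estimated one; feeder fibroblasts in the cultures could be a source. The 19 fibroblast markers with a control mean under 5 had a median rise of -0.0508 in Q111 and 0.02 in Q20, and 15 stayed under 5; Dcn at 2.19, Lum at 2.38 and Col3a1 at 3.11 did not rise, as feeders would need, while Col1a1 went from 3.73 to 8.40, Col1a2 from 2.68 to 5.08 and Col5a2 from 2.76 to 4.20. Genes on the shifted chromosomes did not carry the rise, since primed epiblast members elsewhere had a median rise of 1.58 in Q111. Repeat length alone would leave Q20 near the controls. Over the primed epiblast, trophoblast and fibroblast lists, picked after their rise was seen, the mean rise in Q20 was 90.5% of that of Q111. The filter in part set the fibroblast values. Medians in Q50 and Q20 were 0.79 and 1.41 for primed epiblast, 0.32 and 1.79 for fibroblast markers and 1.42 and 1.07 for trophoblast. With the preset correlation, camera also gave a rising slope with length for primed epiblast and fibroblast markers. A part of the rise that grows with length is therefore not excluded. The rise in Q20 could come from a difference between the knock-in and control cultures that does not need a long repeat. Clone and targeting are such differences, and neither was tested directly. In the knock-out the medians were -0.27 for primed epiblast, -0.54 for trophoblast and -0.10 for fibroblast markers, so the rise was absent there. This argues against targeting of Htt as such, if the knock-out was also made by targeting. It leaves clone and the knock-in allele itself open.

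The knock-out changes could reflect structure among control and knock-out arrays and not the loss of Htt. Over 200 divisions into independent sets of arrays the lowest r between 2 estimates was 0.379 and the median 0.779, so the changes were shared between sets. This is weak evidence, since a clone difference between all knock-out and all control arrays would give the same result.

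Other splits of the arrays were fitted to ask whether chance alone gives as many calls. As many calls came in 1 of 100 splits for the knock-out, the real one (highest other 98). They came in 1 of 84 for Q20 (11), 1 of 84 for Q50 (210), 1 of 84 for Q91 (794) and 1 of 84 for Q111 (121). A chance division of the arrays is excluded only if the arrays are independent, which is not known here. A chance difference between clones would give the same result and is not excluded. For the trend 12 of 24 orders of the lines gave as many, and the highest other gave 582, so chance cannot be excluded.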
